A study of Trichophyton mentagrophytes with 6 samples.

How the data were processed

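Poly(A)-selected mRNA from 3 HQD-treated and 3 untreated cultures of Trichophyton mentagrophytes XM109 was fragmented, copied with random hexamers and sequenced as paired-end reads on a DNBSEQ instrument, per the labels' protocols. The submitters' processing notes list Bowtie2 2.2.5, StringTie 2.1.2 and DESeq2 1.4.5 without saying which step each was used for. The genome build, the annotation, the strand setting of the counting and any filter on genes are not given in the sources used here, so overlapping genes, antisense partners and near-identical copies may share reads in ways that cannot be separated here. The whole-number read counts per gene were deposited as 1 column per library and are unnormalized, with totals between 31540317 and 33152085. The FPKM values (fragments scaled to gene length and library total) were deposited by the authors in a second table of the same genes. Among 6207 genes with more than 200 counts in every library, the ratio of count to FPKM, after a constant per library, stayed within 1% of the gene's median in all libraries for 99% of genes, and the same genes were at 0 in both. The FPKM table therefore holds the same measurement as the counts on another scale, and it was used only as an alternative. All columns of both tables were matched to samples by library name, and 0 columns were left over.

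Samples were grouped by their titles. No label gives a batch, a date or a shared culture. Equal replicate numbers were not taken as pairs in the main fit. The labels call the replicates biological and do not say how separate the cultures were, so p-values measure the spread between these libraries.

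Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter on low counts (a minimum count of 10 and a minimum total of 15) and group as the only term. This left 8014 genes and removed 251. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. A second count required at least a 2-fold difference. The coefficient of variation between replicates was 0.359 in the common fit. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM scaled by TMM, given as the mean ± SD of 3 libraries. For a gene with no count in a group, the bound is 3 counts over the group's libraries and covers counting error only, as reads without molecular identifiers are not independent molecules. Correlations between libraries used log2 CPM with a prior count of 2.

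Before the data were examined, the design, the alternatives, 32 gene lists and the rule for naming genes were fixed. The lists were patterns for product names, and since 0 identifiers could be matched to names, 0 lists were tested. The rule for tables without names was applied: the 2 largest rises and the 2 largest falls among genes with an adjusted p under 0.05, at least a 2-fold change, at least 10 CPM in a group and no overlap between groups. Genes outside this rule are described without an identifier. The classes by abundance, the MSTRG class, the follow-up of HQD replicate 3 and the checks on gene numbers were chosen after the data had been seen, except the correlation of neighbouring gene numbers between controls, which was chosen before its value was seen.

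The alternatives were DESeq2 size factors and library size alone in edgeR, no filter beyond a total above 0, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a term for the replicate number, each library left out in turn, and limma with a trend on log2(FPKM + 1) or log2(FPKM + 0.1) with and without a minimum mean FPKM of 1. Fits added later left out both HQD replicate 3 and control replicate 1, or used limma-voom with library weights. A set test of the MSTRG loci used camera with a preset correlation of 0.01 and with an estimated one.

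The tests were tested on simulated data drawn from the real means, library sizes and dispersions of HQD against control, with 200 changed genes, 50 at each of 4 fold sizes. On 7999 genes, edgeR made 96 calls of which 2 were false, limma-voom 97 of which 4 were false, and DESeq2 138 of which 29 were false. At 2-fold, edgeR recovered 6% and DESeq2 24% of the changed genes. Noise was drawn independently for each gene, so no simulated library stood apart as a whole, unlike in the real data.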

Results

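The data consisted of poly(A)-selected RNA-seq libraries of Trichophyton mentagrophytes strain XM109, a dermatophyte fungus that grows on keratin-rich tissue such as skin, hair and nails. The series asked which fungal genes respond to HQD, Huangqin decoction, a traditional Chinese herbal preparation named after the root of a Scutellaria species. Cultures started from spores were kept for 5 days at 28 °C either with HQD at its minimal inhibitory concentration, 3.13 mg/mL, or in drug-free broth, with 3 libraries per group that the labels call biological replicates. The deposited tables listed 8265 genes. Of these, 7860 carried TMEN identifiers and 405 carried MSTRG identifiers, the prefix that the assembler StringTie gives to loci it assembles itself. The tables do not pair identifiers with gene names or coordinates, so genes are given by identifier and no pathway was tested. Total counts were similar in all libraries, between 31540317 and 33152085, with a mean of 32511333 ± 762672 under HQD and 32154691 ± 606162 in the controls (SD, n = 3 each). Between 7715 and 7885 genes reached at least 1 CPM (counts scaled to a common library total) in each library, and 157 genes had no count in any library.

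The libraries were first compared with one another, since the spread within groups sets what a comparison of the groups can show. HQD replicates 1 and 2 stood well apart from the controls, whereas HQD replicate 3 resembled 2 of them. Across the 8014 genes that passed the count filter, HQD replicate 3 correlated with control replicates 2 and 3 at r = 0.968 each, and with HQD replicates 1 and 2 at only 0.931 and 0.937. Control replicates 2 and 3 were very alike (r = 0.996), while control replicate 1 correlated with them at 0.949 and 0.953. These correlations are across genes, which are not independent replicates. The log2 differences from control replicate 2 had an SD over genes of 0.532 in HQD replicate 3, compared with 0.698 in control replicate 1, 0.949 in HQD replicate 2 and 1.02 in HQD replicate 1. The pair of similar controls still differed by more than counting noise, with a chi-square of 24.6 per degree of freedom where counting noise alone gives about 1. This does not show that they came from separate cultures. Both were kept as separate replicates because the labels call them so. If they shared a culture, the p-values below could be too small. The fits below that leave out control replicate 2 or 3 keep only 1 of the pair, and each called 1 gene, TMEN_10013. The other pairs within a group gave between 557 and 987.

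**Figure D1:**
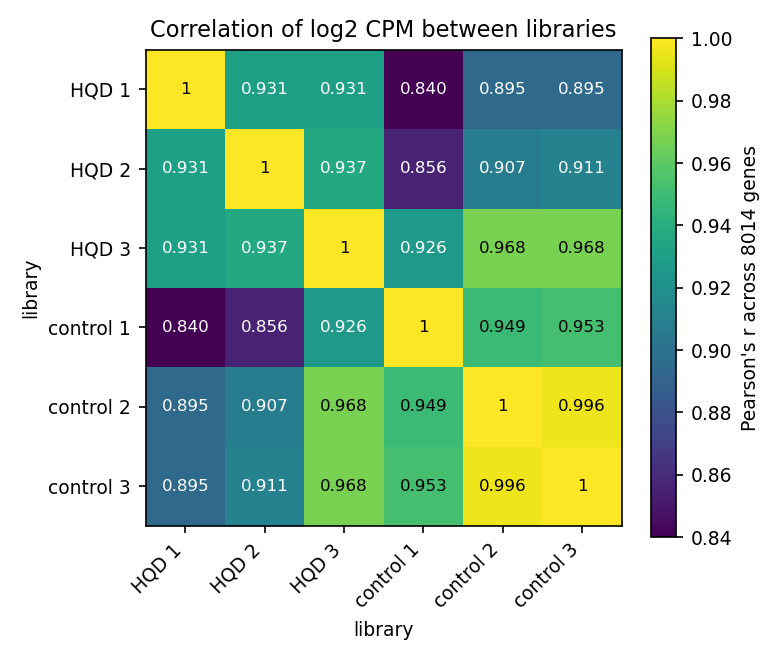
Pearson correlation (no unit, colour scale and printed values) of log2 CPM between the 6 libraries, with the libraries in the same order on both axes. HQD replicate 3 sits at 0.968 with control replicates 2 and 3, above its 0.931 and 0.937 with the other HQD libraries, and the lowest value, 0.84, is between HQD replicate 1 and control replicate 1.

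The comparison of HQD with control asked which transcripts differed after 5 days at the inhibitory concentration. A difference in growth stage or biomass between the groups cannot be separated from a direct effect of HQD with these libraries. Expression of 33 of the 8014 tested genes differed, 30 of them higher and 3 lower under HQD (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). All 33 differed by at least 2-fold, and in each of them every HQD library lay on the same side of every control. The log2 fold changes of the 30 genes that rose ranged from 1.55 to 7.84 with a median of 2.78. Of these, 25 rose at least 4-fold, and 17 averaged 100 CPM or more under HQD. None of the 30 was silent in the controls, where 10 averaged under 10 CPM and none under 1 CPM. HQD replicate 3 had the lowest level of the HQD libraries for 25 of the 30 genes, and HQD replicate 1 the highest for 20.

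**Figure D2:**
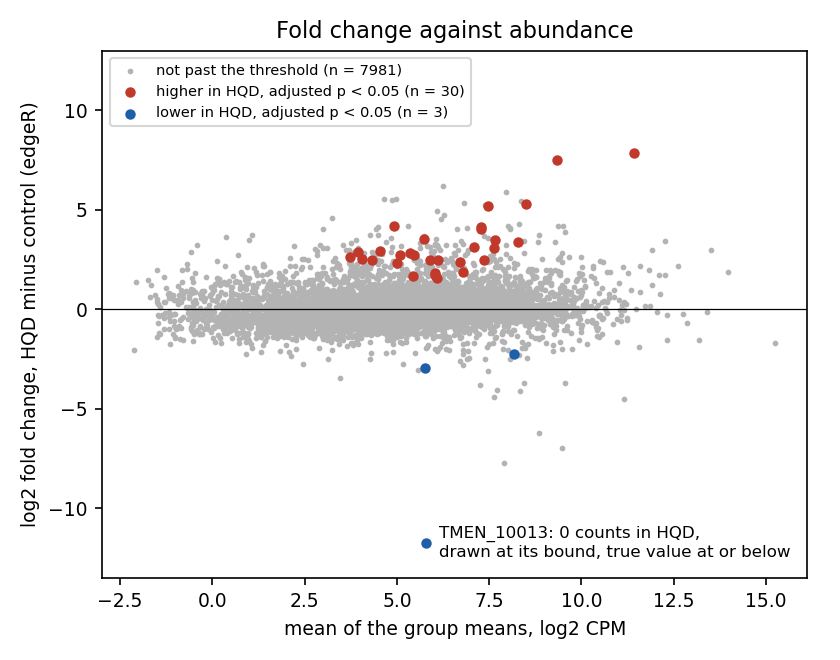
Log2 fold change, HQD minus control, from the edgeR fit (vertical axis) against the log2 of the average of the mean CPM values of the groups (horizontal axis), 1 point per tested gene. The 30 genes that rose (red) lie between 1.55 and 7.84, and of the 3 that fell (blue) TMEN_10013 is drawn at its lower bound of a 3440-fold difference because no HQD library had a count.

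The largest rise was that of TMEN_5238, from 23.8 ± 16.9 CPM in the controls to 5460 ± 5695 CPM under HQD (SD, n = 3 each). Its log2 fold change was 7.84 with a standard error of 1.13 (edgeR adjusted p = 0.044). The HQD libraries held 12030, 2404 and 1945 CPM, all far above the highest control at 42.8 CPM. TMEN_7724 rose from 7.16 ± 2.15 to 1285 ± 1310 CPM (SD, n = 3), a log2 fold change of 7.49 with a standard error of 0.97 (edgeR adjusted p = 0.0408). Its 3 HQD libraries held 2766, 813 and 276 CPM. These were the only rising genes that averaged at least 1000 CPM under HQD. Neither call held when HQD replicate 2 was left out (edgeR adjusted p = 0.0911 for TMEN_5238 and 0.0895 for TMEN_7724) or when any 1 control was left out (between 0.137 and 0.189 for the pair of genes), although the log2 fold changes stayed at 7.28 or above in those fits. Without HQD replicate 1 both calls held, at smaller log2 fold changes of 6.51 for TMEN_5238 and 6.25 for TMEN_7724.

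TMEN_10013 had no count in any HQD library and 4657, 3325 and 3581 counts in control replicates 1, 2 and 3. Its control level was 112 ± 7.07 CPM (SD, n = 3). With a floor of 3 counts over the 3 HQD libraries together, equal to 0.0326 CPM, its level under HQD was at least 3440-fold lower (edgeR adjusted p = 0.000572). The floor covers counting error only. The call held under all 19 alternative settings, with adjusted p between 1.98e-27 and 0.0265. TMEN_2470 fell from 95.6 ± 19.2 to 12.3 ± 6.96 CPM (SD, n = 3), a log2 fold change of -2.96 with a standard error of 0.42 (edgeR adjusted p = 0.044). HQD replicate 3 kept the most of it, 20.1 CPM against 9.95 and 6.81 in the others. Its call was lost without HQD replicate 1 or 2 (edgeR adjusted p = 0.0992 and 0.0994) and without any 1 control (between 0.137 and 0.173). The log2 fold changes in those fits lay between -3.1 and -2.67. The third gene that fell went from 477 ± 101 to 99.0 ± 32.2 CPM (SD, n = 3), a log2 fold change of -2.27 with a standard error of 0.34 (edgeR adjusted p = 0.044). Its call was also lost when any 1 control was left out, as TMEN_10013 was then the only gene of the 33 still called.

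**Figure D3:**
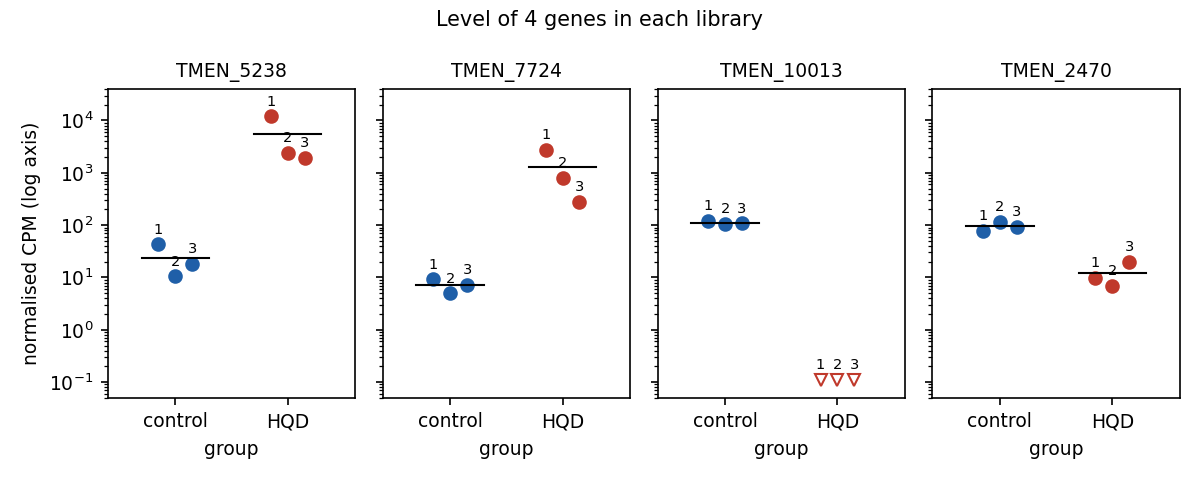
Normalised CPM on a log axis of 4 genes in the 3 control (blue) and 3 HQD (red) libraries, with the replicate number above each point and a bar at the group mean. TMEN_5238 and TMEN_7724 are higher and TMEN_2470 lower in every HQD library than in every control, and the open triangles for TMEN_10013 mark counts of 0, drawn at the 3-count limit of 0.11 CPM.

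Of the 8014 tested genes, 1679 had an unadjusted p under 0.05, with 1004 of them higher and 675 lower under HQD. The other 9 splits of the 6 libraries into groups of 3 gave between 93 and 796 such genes, the most when control replicate 1 took the place of HQD replicate 3. Those splits held HQD and control libraries in both groups, so they do not give a null level. The HQD and control libraries did not overlap for 1230 genes that were higher and 1198 that were lower, 30.3% of those tested, where chance gives 10% on average. A fitted rise of 8-fold or more was found for 67 genes, and a fitted fall of that size for 13, that did not pass the adjusted threshold. In 56 of the 67 and 12 of the 13 the HQD and control libraries did not overlap. In data simulated with the dispersion of each gene, the same edgeR test on 7999 genes recovered 6% of genes changed 2-fold, 84% of those changed 4-fold and 96% of those changed 8-fold. The simulated noise was independent between genes, and no simulated library stood apart from its group as HQD replicate 3 and control replicate 1 did. These shares are therefore not the sensitivity of the test in the real libraries.

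The most abundant transcripts varied between libraries of the same group. The gene with the highest mean in the controls held 59791 ± 8600 CPM there and 18574 ± 19878 CPM under HQD (SD, n = 3 each). Its HQD libraries held 14070, 1337 and 40320 CPM, and the difference did not pass the test (edgeR adjusted p = 0.465). The gene with the highest mean under HQD had 25363 ± 10070 CPM there and 6885 ± 4092 CPM in the controls, and also did not pass (edgeR adjusted p = 0.268). Together the 10 most abundant genes of each library took 12.6 ± 0.47% of the counts under HQD and 14 ± 0.56% in the controls (SD, n = 3 each).

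The genes that passed the test were found at all levels of abundance. Of the 30 that rose, 6 were in the lowest of 3 equal classes of genes by mean level, 15 in the middle class and 9 in the highest, and each class held 1 of the genes that fell. Among genes with an unadjusted p under 0.05, the most abundant class had 377 higher and 117 lower under HQD, and the least abundant class 293 higher and 330 lower. The median log2 fold change was -0.12 in the least abundant class, 0.00 in the middle and 0.10 in the most abundant. Of the 384 tested MSTRG loci, 3 rose and 0 fell, and 58 higher and 43 lower loci had an unadjusted p under 0.05. The share of MSTRG loci called did not differ from that of the TMEN genes, 27 of which rose and 3 fell among 7630 (Fisher's exact test, two-sided p = 0.209). An unadjusted p under 0.05 was more frequent among MSTRG loci, at 26.3%, than among TMEN genes, at 20.7%, a difference that was not tested; the MSTRG loci were also less abundant, with a median of 6.95 against 47.3 CPM. As a set the MSTRG loci did not shift in one direction relative to the other genes (camera p = 0.89 with a preset correlation and p = 0.874 with an estimated correlation).

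The number of genes called changed when single libraries were left out, and the calls of rising genes lay near the threshold. The 30 rising genes had edgeR adjusted p between 0.0205 and 0.0497, and the smallest value of an uncalled gene was 0.0509. At an edgeR adjusted p under 0.1 there were 274 genes, 224 higher and 50 lower under HQD. The 33 are therefore not a set set apart from the genes just past the threshold. Without HQD replicate 3, edgeR called 621 genes, 436 higher and 185 lower under HQD, among them all 33 of the full comparison. Without control replicate 1, 2 or 3 it called 2, 1 and 1 genes, all lower under HQD, so that 0 of the 30 rising genes passed in any of these fits. With fewer residual degrees of freedom there, edgeR still gave 1251, 1201 and 1145 genes an unadjusted p under 0.05, against 1679 with all libraries. Without HQD replicate 1 it called 18 and without HQD replicate 2 it called 7. Scaling by library size alone shifted the median log2 fold change of all genes from 0.01 to -0.17 and gave 33 genes higher and 8 lower, and the deposited FPKM values gave 37 higher and 15 lower. DESeq2 called 791 genes on the same counts, 573 higher and 218 lower, including all 33.

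The response seen in HQD replicates 1 and 2 was then followed in HQD replicate 3 with separate control libraries, a check chosen after the data had been seen. Relative to control replicate 1, 237 genes were at least 4-fold higher and 119 at least 4-fold lower in both HQD replicates 1 and 2. In HQD replicate 3, 226 of the 237 (95.4%) were higher and 88 of the 119 (73.9%) were lower than the mean of control replicates 2 and 3. The matching shares over all genes were not computed, so these percentages have no background beside them. Control replicate 1 stood apart from the other controls, so part of each set may reflect that library. The median log2 difference of HQD replicate 3 from those controls was 0.84 in the rising set and -0.39 in the falling set. The sizes in HQD replicates 1 and 2 are not set beside these, as the genes were chosen by them. No p-value is given, since genes are not replicates and HQD replicate 3 is 1 library.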

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

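The direction of all 33 genes was the same in every setting tried, planned or added. These settings could hardly have reversed it, as they reuse the same libraries and the groups did not overlap for any of the 33. The number called was not stable. With DESeq2 size factors edgeR called 35 genes, with library size alone 41, without a filter 32 and with a 1 CPM filter 33. limma on log2(FPKM + 1) of all genes called 34, with 23 higher and 11 lower under HQD. Of these 34, rising or falling, 23 were among the 33. limma-voom called 13 genes, all among the 33, the FPKM table with a minimum mean gave 52 with a pseudocount of 1 and 63 with 0.1, and DESeq2 gave 791 (714 at least 2-fold). Leaving out 1 library gave between 1 and 621 genes, and between 1 and 610 at least 2-fold. The low end came from leaving out a control and the high end from leaving out HQD replicate 3. A term for the replicate number (the replicate block) gave 53 genes, 26 of them among the 33. The deviations of same-numbered libraries from their group means correlated at -0.07, -0.04 and -0.10, and none correlated best with its own number. Deviations from a mean of 3 libraries are tied to one another within a group, so these values cannot show whether same-numbered libraries shared a culture day. Of the fits added after the data had been seen, edgeR without HQD replicate 3 and control replicate 1 called 338 genes, DESeq2 without them 1665 (1297 at least 2-fold), and limma-voom with library weights 512 (482 at least 2-fold), with 30, 33 and 33 of the 33 among them. The causes of these shifts were not tested, except that fits without a library have fewer residual degrees of freedom. Mean correlations between libraries ranged from 0.931 to 0.937 within HQD, from 0.949 to 0.996 within the controls and from 0.884 to 0.924 between groups when 1 library was left out, the highest value in the controls coming without control replicate 1. The alternatives planned for gene lists were not run, as no list could be matched. Depth was not the limit for genes at 100 CPM, about 3000 counts per library; the spread between replicates was.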

Other observations

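All tests below were chosen after the result they bear on had been seen, except the correlation of neighbouring gene numbers between controls. In addition to the genes of the report, runs of consecutive TMEN numbers moved together. Among genes with an unadjusted p under 0.05 and at least a 2-fold change, 213 of the 639 that were higher under HQD had a neighbour by number that was also higher, where 1000 shuffles of the numbers gave 98.6 on average and 141 at most. For the 299 lower genes it was 58, against 22.4 on average and 47 at most. Both p-values, 0.001, are the smallest that the shuffles can give. The longest run held 7 genes among the higher and 3 among the lower.

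No other split of the 6 libraries into groups of 3 gave a call. The real split gave 33 genes, and the highest of the other 9 gave 0. Each of those 9 put HQD and control libraries together in both groups. A real difference between HQD and control would then widen the spread within groups, so their 0 is not a null level. With 10 splits, of which 1 (the real one) reached that number, no share under 0.05 is possible.

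TMEN_10013 was the only gene of the tables with more than 300 counts in some library and 0 in another. It stood apart from the other falling genes. Of 1897 other genes with at least 3000 counts in every control, 0 came under 1% of their lowest control in all HQD libraries, and the next lowest kept 5.75%. The gene was followed up because it was the most extreme fall, so this cannot decide whether its fall was graded. Loss of a stretch of several genes is argued against, if numbers follow position. Of the 9 genes numbered within 5 of it, 0 were at 0 in an HQD library while present in the controls. Assignment of its reads to another gene stays open, because 79 other genes gained at least 106.6 CPM, its lowest control level, in every HQD library, although none was an MSTRG locus. A single-gene difference in the DNA of the cultures, or complete silencing under HQD, may also account for it and cannot be separated with RNA counts.

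HQD replicate 3 lay close to the controls. A control library under an HQD label is argued against, as far as control replicate 1 shows how control cultures vary. The test used 114 genes at least 4-fold higher in HQD replicates 1 and 2 than in control replicates 2 and 3. Of these, 66.7% were also at least 2-fold higher in HQD replicate 3 and 7.89% in control replicate 1. Of 43 genes at least 4-fold lower the shares were 53.5% and 20.9%. With control replicate 2 or 3 as the one left out, its share was 0%. That adds nothing, because the other of these nearly alike libraries was then in the pair it was compared with. The comparison therefore rests on control replicate 1. A control culture that had strayed towards HQD is not covered by this test. Control replicate 1 lay farther from HQD replicate 1 (r = 0.84) than control replicates 2 and 3 did (0.895 each), and those 2 were nearly alike. Mixing with RNA or reads of the 3 control libraries is argued against too, since 8 of 5053 genes of at least 20 CPM in every control were under 1 part in 10 of the lowest control, which limits such a share to 10%. Mixing with RNA of another control culture stays open: 34 genes were under 1 part in 3 of control replicates 2 and 3 in HQD replicate 3, but 146 were in control replicate 1. A control culture as the source, mislabelled or mixed in at a sizeable share, would have to lack TMEN_10013 transcripts. That gene, itself 1 of the 8 above, had 0 counts in HQD replicate 3 and at least 106.6 CPM in every control. It is 1 gene with an unexplained absence, so it does not settle the question. The same response at a smaller size is a candidate explanation. Over all genes the covariance of HQD replicate 3 with another HQD library was 0.473 and 0.399 of that of the remaining one, each measured against separate controls. Mixing with RNA of another control culture could give such intermediate ratios too, so they do not favour a smaller response over it. Differences in exposure, growth stage or biomass between the cultures stay open and untested.

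The fold changes of genes with adjacent numbers correlated at r = 0.166 over 7325 pairs, where the highest of 1000 shuffles was 0.0353. Reads shared between overlapping next-door genes are argued against as the whole cause, because the correlation was 0.0864 at a distance of 2, above the 0.028 that a chain of shared reads would pass on, and 0.0724 at a distance of 3. The pattern may not be particular to HQD, as control replicate 1 against control replicates 2 and 3 gave 0.155 at a distance of 1; at a distance of 2 it gave 0.0584, above the 0.0362 that shuffles reached, and at 3 it gave 0.0217, within that range. The difference between the contrasts at a distance of 3 was not tested. Joint regulation of neighbouring genes and shared sequence properties such as GC content stay open.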
